A study of Pseudoalteromonas sp. SM9913 with 3 samples.

How the data were processed

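Total RNA of wild-type *Pseudoalteromonas* sp. SM9913 was isolated with a Tiangen RNAprep Pure Cell kit and sequenced on an Illumina HiSeq 2000, per the labels' protocols. The labels give 3 libraries, 1 each for planktonic cells, the initial pellicle (day 1) and the mature pellicle (day 5), and they define the groups used here. The aligner, the counting rule, the treatment of reads that map to several places, the strand setting and the genome build are not given in the sources used here. Removal of ribosomal RNA is not given either. Paralogous and overlapping genes are therefore uncertain where reads could be split between them.

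The authors deposited a table of whole-number read counts for 3647 genes with locus tag, product text and length. The tags fall into 2 series, PSM_A (3031 genes) and PSM_B (616 genes). The lengths run from 114 to 4842 bases and 100% are divisible by 3, so they are coding lengths. The table held 0 genes for ribosomal or transfer RNA. Counts in each library summed to the mapped total that stands in its column name, per the file headers. The deposited RPKM values (reads per kilobase of gene, scaled to the mapped total) equalled count divided by length and total, to within 5.09e-11. The authors' deposited coverage values, the signal per gene, are a ratio that reached 1.06 in the initial pellicle, and they were used only in that check. The authors also deposited a table for each pellicle against planktonic cells, with a log2 ratio of RPKM in which 0.001 stood for an RPKM of 0, a p-value and a false discovery rate. The test behind the authors' deposited p-value is not given in the sources used here. With 1 library per stage it can compare only the reads of 2 libraries, and 83.2% and 81.8% of genes passed a false discovery rate of 0.001. No gene symbols or coordinates were used, so genes are named by tag and product.

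Genes with at least 10 counts in at least 1 library were kept, which left 3552 and removed 95. Libraries were scaled by TMM in edgeR 4.0.16 under R 4.3.3, with factors of 0.838, 1.23 and 0.971 for planktonic, initial and mature. The log2 fold change was the difference of edgeR's log2 CPM with a prior count of 2. The ratio of counts had an exact (Clopper-Pearson) 95% interval. A gene was called higher or lower at a fold of at least 2 with an interval that excluded 1. No test was run and no p-value was computed, because 1 library per group leaves no residual degrees of freedom. A count of 0 was taken to allow up to 3 counts. Reads without molecular identifiers are not independent molecules, so intervals and limits cover counting error only. With counts of 1 to 3 in a library, the ratio is given with its interval in place of the fitted fold.

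Before the data were examined, 30 gene lists, the 2-fold rule, the alternatives and the rule for named genes were fixed. Of these lists 28 had at least 3 measured members, type VI secretion had 2 and amino acid biosynthesis, defined by gene symbols, had 0. Each list's median was placed among 10000 random lists of the same size, matched on mean expression by decile (10 bins). Genes named were the 6 largest and 6 smallest log2 fold changes per comparison with an informative product, among genes with at least 50 counts in the higher library. Named too were the 2 most different members of each list described and every tyrosine degradation gene. Which products count as informative was settled after the leading genes had been seen. Runs of neighbouring genes, corrected lists and the patterns at 4-fold were chosen after the values had been seen.

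List patterns matched product text inside words, with some faults. The flagellum list took 41 chemotaxis genes because a motor gene's name lies inside the word chemotaxis, and corrected results are given beside it. The toxin-antitoxin list took genes whose text mentions release, such as PSM_A2096, a ribosome releasing factor, and held no toxin gene. Its median log2 fold changes were -1.42, -1.61 and -0.31, it lay below the central 95% in both comparisons with planktonic cells, and it is not described further. The mobile element list took 3 Tol genes, which were removed in the corrected list. Citrate and malate patterns took PSM_A2985 and PSM_A2986, of leucine synthesis, and methylcitrate genes PSM_A1291 to PSM_A1293. Cold-shock gene PSM_A1312 also stands in the heat shock list, anti-sigma factor gene PSM_A2993 in the sigma factor list and PilZ gene PSM_A0906 in the pilus list. The oxidase list missed PSM_A0855 to PSM_A0857, whose text reads ubiquinol oxidase, and the bd-type oxidase genes PSM_A2081 and PSM_A2082. The list named for secreted proteases and peptidases was defined by protease and peptidase text, including aminopeptidases and oligopeptidases. It did not require that a product be secreted. Only the flagellum, mobile element and toxin-antitoxin lists were corrected.

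The procedure was tested on simulated counts for the 3552 genes with 200 genes changed. With counting error only, 98%, 98% and 100% of genes changed 2.5-fold were recovered in the comparisons initial against planktonic, mature against planktonic and mature against initial, and 0.0597% of unchanged genes were called in each. With an assumed biological coefficient of variation of 0.2, recovery was 74%, 82% and 84%, and 2.30%, 1.97% and 2.00% of unchanged genes were called. The counting intervals then held the true ratio for only 27.0%, 29.9% and 26.4% of unchanged genes. Of 100 random lists drawn from all simulated genes, changed ones included, 3 to 7 fell outside the central 95% across these simulations. The simulated noise was independent between genes, so these rates do not cover lists of neighbouring genes that vary together. As many simulated genes were raised as lowered, and most were unchanged. In the data, 933 genes were higher and 835 lower in the initial pellicle than in planktonic cells. Error in the scaling is therefore not covered by these rates.

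Alternatives were size factors from DESeq2 1.42.0 (0.790, 1.24 and 0.980), total counts, no filter, a minimum of 100 counts, a prior count of 0.5, a 4-fold threshold, the authors' deposited log2 ratio, and random lists drawn as runs of neighbouring genes, which were not matched on expression. Overlap with the shared planktonic library was simulated 100 times with Poisson counts and with coefficients of variation of 0.2 and 0.4. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.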

Results

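*Pseudoalteromonas* sp. SM9913 is a marine bacterium that grows as free cells in shaken medium and forms a pellicle, a biofilm at the surface of standing liquid. RNA from the wild type was sequenced at 3 stages. Planktonic cells came from a shaken culture at an optical density (OD600) of about 1. Pellicles came from static cultures started at about 0.1 and were taken after 1 day (initial pellicle) and after 5 days (mature pellicle). Each stage had 1 library. The table held 3647 protein-coding genes, of which 1236 carry a hypothetical product. Over the 3552 genes measured, counts summed to 17151764 in the planktonic, 18442749 in the initial pellicle and 17806667 in the mature pellicle library. A count of 0 allowed up to 0.175, 0.163 and 0.168 CPM (counts scaled to library size) in these libraries. The 100 most abundant genes took 53.4% of the planktonic counts, 38.7% in the initial pellicle and 43.9% in the mature pellicle. The most abundant gene was PSM_A0241, elongation factor G, in planktonic cells (2.08% of counts), PSM_A2033, a TonB-dependent receptor, in the initial pellicle (1.05%) and PSM_A0976, outer membrane protein W, in the mature pellicle (2.46%).

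With 1 library per stage no difference between stages had a replicate check. Shaking and the time or density at collection differed along with the stage. Their effects cannot be told apart from those of the pellicle itself. Fold changes and intervals compare these 3 libraries, and the 95% intervals, given on the log2 scale, cover counting error only. A gene was counted as higher or lower when it differed at least 2-fold and its interval excluded a ratio of 1. Fold changes were relative to a scaling that set the bulk of genes to no change (medians of 0.01, 0.06 and -0.02 over 3552 genes in the comparisons initial against planktonic, mature against planktonic and mature against initial). Scaling to total counts instead shifted the log2 scale by 0.55, 0.21 and -0.34, respectively, and genes with few counts by somewhat different amounts because of the prior count.

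The comparison of the initial pellicle with planktonic cells asked which genes set the early biofilm apart. Genes of the pooled list for breakdown of fatty acids and branched-chain amino acids were higher in the initial pellicle, often by more than an order of magnitude. So were genes for tyrosine breakdown, TonB-dependent uptake, curli fibres, proteases and peptidases, and lateral flagella. Genes of the cytochrome o ubiquinol oxidase, a proton-pumping terminal oxidase of aerobic respiration, were the most reduced with a known product, at 88.4-fold to 299-fold lower. Ribosomal protein genes were also lower, 48 of 55 by at least 2-fold, or 21 with total counts. In all, 933 of 3552 genes were at least 2-fold higher and 835 at least 2-fold lower, and 89.4% of genes had an interval that excluded 1. With total counts 1341 were higher and 371 lower.

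Catabolic genes gave the largest list median. Of 20 measured genes for fatty acid degradation and branched-chain amino acid catabolism, 18 were higher and 1 lower, with a median log2 fold change of 4.21 that lay above all 10000 random lists (percentile 100). PSM_A1500, methylmalonate-semialdehyde dehydrogenase of valine breakdown, was 105-fold higher and the acyl-CoA dehydrogenase PSM_A1501 was 83.6-fold higher. Both lie in a run of branched-chain amino acid genes (PSM_A1495 to PSM_A1504), and the list does not separate such genes from those for fatty acids. Outside this list, the putative decarboxylase PSM_B0022 was 148-fold higher, with 174 planktonic and 41046 initial pellicle counts, and the alcohol dehydrogenase PSM_B0592 was 129-fold higher. In tyrosine degradation, 6 of 7 genes were higher (median 3.07, percentile 99.95). PSM_A0972, 4-hydroxyphenylpyruvate dioxygenase, which forms homogentisate, the precursor of the brown pigment pyomelanin, was 49.2-fold higher (interval 5.51 to 5.74). PSM_B0404, homogentisate 1,2-dioxygenase, which opens the homogentisate ring, was 20.8-fold higher (4.21 to 4.56). The further steps PSM_B0403, maleylacetoacetate isomerase, and PSM_A0971, fumarylacetoacetase, were 15.7-fold and 8.40-fold higher. Phenylalanine 4-monooxygenase PSM_A2107, which makes tyrosine, was 4.96-fold higher and its partner PSM_A2106, pterin-4-alpha-carbinolamine dehydratase, 3.97-fold. The fumarylacetoacetate hydrolase family gene PSM_A0663 had a log2 fold change of 0.34. Of 4 histidine degradation genes, 2 were higher (list median 2.54, percentile 99.17), namely histidine ammonia-lyase PSM_A0286 at 18.8-fold and urocanate hydratase PSM_A0287 at 17.0-fold. Among 27 genes of the tricarboxylic acid cycle and glyoxylate shunt, 13 were higher and 6 lower (median 0.22, percentile 95.8). The higher ones included PSM_B0064, isocitrate lyase, the entry of the glyoxylate shunt, at 74.7-fold, and PSM_A1292, methylcitrate synthase of propionate breakdown, at 42.3-fold. Of 11 genes for glycolysis and gluconeogenesis, 2 were higher and 5 lower, with a median of 0.32 and a mean of -0.25. PSM_A0722, phosphoenolpyruvate carboxykinase, a gluconeogenic enzyme, was 5.74-fold higher and the glyceraldehyde 3-phosphate dehydrogenase PSM_A1396 was 8.64-fold lower.

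At the cell surface, TonB-dependent receptors, the outer membrane gates for iron complexes and large nutrients, had 23 of 37 genes higher and 5 lower (median 2.02, percentile 100). PSM_A2033 was 97.4-fold higher (interval 6.53 to 6.69), PSM_A2366, a receptor for ferric iron, 76.0-fold, and PSM_A1233, the ferric enterobactin receptor, 63.7-fold. The list for iron uptake and storage, which shares some of these receptors, had 7 of 20 genes higher and 3 lower (median 0.52, percentile 96.7). PSM_A0976, outer membrane protein W, was 134-fold higher (6.96 to 7.18). Of 5 genes for adhesins and matrix proteins, 4 were higher and 1 lower (median 4.04, percentile 99.96). The higher genes belong to curli, the amyloid fibres of many biofilms: PSM_B0249, the major curlin subunit, was 76.0-fold higher and the assembly gene PSM_B0247 was 23.6-fold higher. Of 27 genes in the list named for secreted proteases and peptidases, 15 were higher and 2 lower (median 1.91, percentile 100). The serine protease PSM_A2685 was 88.7-fold higher and PSM_B0251, the extracellular protease deseasin MCP-01, 69.6-fold. All 12 genes of type II secretion, the route by which many extracellular enzymes leave the cell, were higher (median 1.47, percentile 99.51), among them PSM_A0730 (3.37-fold) and PSM_A0726 (3.29-fold). This list lay at percentile 93.7 of random lists built from runs of neighbouring genes, inside their central 95%. For nutrient limitation, 9 of 14 nitrogen and phosphate starvation genes were higher and 1 lower (median 1.76, percentile 99.9), led by alkaline phosphatase PSM_A3086 (23.7-fold) and the phosphate transporter PSM_A2461 (log2 fold change 4.32). Genes for polysaccharide, capsule and lipopolysaccharide synthesis went the other way, with 9 of 18 lower and 1 higher (median -0.95, percentile 1.71). Polysaccharide export gene PSM_A1270 was 3.49-fold lower and polysaccharide deacetylase PSM_B0447 was 4.61-fold higher. With total counts, 2 members were lower and 2 higher.

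Among motility genes, those of the lateral flagellum, which many marine bacteria use to move over surfaces, were higher in the initial pellicle, 34 of 37 in a run chosen after its values were seen. Without chemotaxis genes caught by an overlap of names, 29 of 69 flagellum and motility genes were higher and 0 lower (median 0.84, percentile 99.98). In the list as fixed, 45 of 110 were higher and 2 lower (median 0.80, percentile 100). PSM_A0897, the lateral flagellin LafA, was 84.3-fold higher (6.23 to 6.59) and PSM_A0891, the lateral L-ring protein, went from 4 to 422 counts (log2 fold change 5.59, interval 4.70 to 7.94). Of 42 chemotaxis genes, 17 were higher and 2 lower (median 0.57, percentile 98.3). The methyl-accepting chemotaxis protein PSM_A2360 was 23.7-fold higher. Against runs of neighbouring genes the chemotaxis list lay at percentile 96.7, inside the central 95%. Of 37 genes for turnover of cyclic di-GMP, the messenger that governs the switch between swimming and attachment in many bacteria, 19 were higher and 4 lower (median 1.05, percentile 99.8). The GGDEF domain gene PSM_A0265 was 4.69-fold and the diguanylate cyclase/phosphodiesterase PSM_B0156 4.67-fold higher. Of 17 pilus genes, 8 were higher and 0 lower (median 0.72, percentile 94.7), PSM_A2709, the pilin PilA, by 3.55-fold.

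Genes for protein synthesis and for the cytochrome o oxidase were lower. The median over 55 ribosomal protein genes was -1.39 (percentile 0), and L34 (PSM_A3127) was 6.11-fold and L31 (PSM_A0299) 4.69-fold lower. Of 38 translation factors and aminoacyl-tRNA synthetases, 22 were lower and 0 higher (median -1.20, percentile 0.2). The central 95% of the matched random lists ran from -1.04 to -0.29 for the ribosomal list and from -1.07 to -0.03 for this one. Matched random lists were thus lower too. They were drawn from all genes of like abundance, members of these 2 lists included. How far other abundant genes share the lower values is therefore not settled. Initiation factor IF-1 (PSM_A1316) was 7.31-fold and elongation factor G (PSM_A0241) 4.22-fold lower. With total counts the lower members numbered 21 ribosomal and 5 translation genes. Of 9 ATP synthase genes, 3 were lower and 0 higher (median -0.93, percentile 32.4), PSM_A3114 by 4.02-fold. In the cytochrome o oxidase gene cluster, PSM_A0857 (subunit 1) was 299-fold lower (-8.94 to -7.81), PSM_A0858 274-fold, PSM_A0855 234-fold and PSM_A0859 139-fold. PSM_A0860, which makes heme O for this oxidase, was 104-fold lower and PSM_A0856, a second gene with the product of subunit 1, 88.4-fold. The list of NADH dehydrogenases and terminal oxidases, which holds PSM_A0858 and PSM_A0859, had 5 of 25 genes lower and 2 higher, with a median of -0.50 that became 0.05 with total counts. Cold shock genes had 4 of 8 lower and 2 higher (median -1.19, percentile 2.95). PSM_B0051 was 8.94-fold lower and the cold-shock RNA chaperone PSM_A1312 was 40.4-fold higher.

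Further large differences included genes of arginine synthesis and of a TonB-linked cluster. Acetylglutamate kinase PSM_A0796, an early step of arginine synthesis, was 132-fold higher (6.60 to 7.70). The putative Tol protein PSM_B0604 had 9 planktonic and 2775 initial pellicle counts, 166-fold higher (6.68 to 8.74). Its neighbour PSM_B0606, a putative TonB-linked transport protein, had 2 and 747 counts, a log2 ratio of 7.89 with an interval of 6.03 to 10.94. Of 28 lists with enough members, 11 had medians above and 4 below the central 95% of random lists. After the flagellum, mobile element and toxin-antitoxin lists were corrected, a choice made after the data were seen, 11 of 27 lay above and 3 below. The toxin-antitoxin list, which held no toxin gene, was removed. Lists with other faults stayed as fixed. With total counts, the higher members numbered 72 in the flagellum list as fixed, 26 in chemotaxis, 11 in iron and 8 in the NADH dehydrogenase and oxidase list, and 2 tricarboxylic acid cycle genes were lower. Glycolysis and gluconeogenesis then had 5 genes higher and 3 lower, cold shock 3 higher and 3 lower, histidine degradation 4 higher and 0 lower, and the lower members numbered 0 in iron, 1 in cyclic di-GMP and 1 in ATP synthase genes. Under that scaling 1341 genes were higher and 371 lower in all, so that 78.3% of the genes past the threshold were higher against 52.8% in the main scaling. In the authors' deposited table, 1325 of 3641 genes were at least 2-fold higher and 368 at least 2-fold lower at a false discovery rate of at most 0.001.

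**Figure D1:**
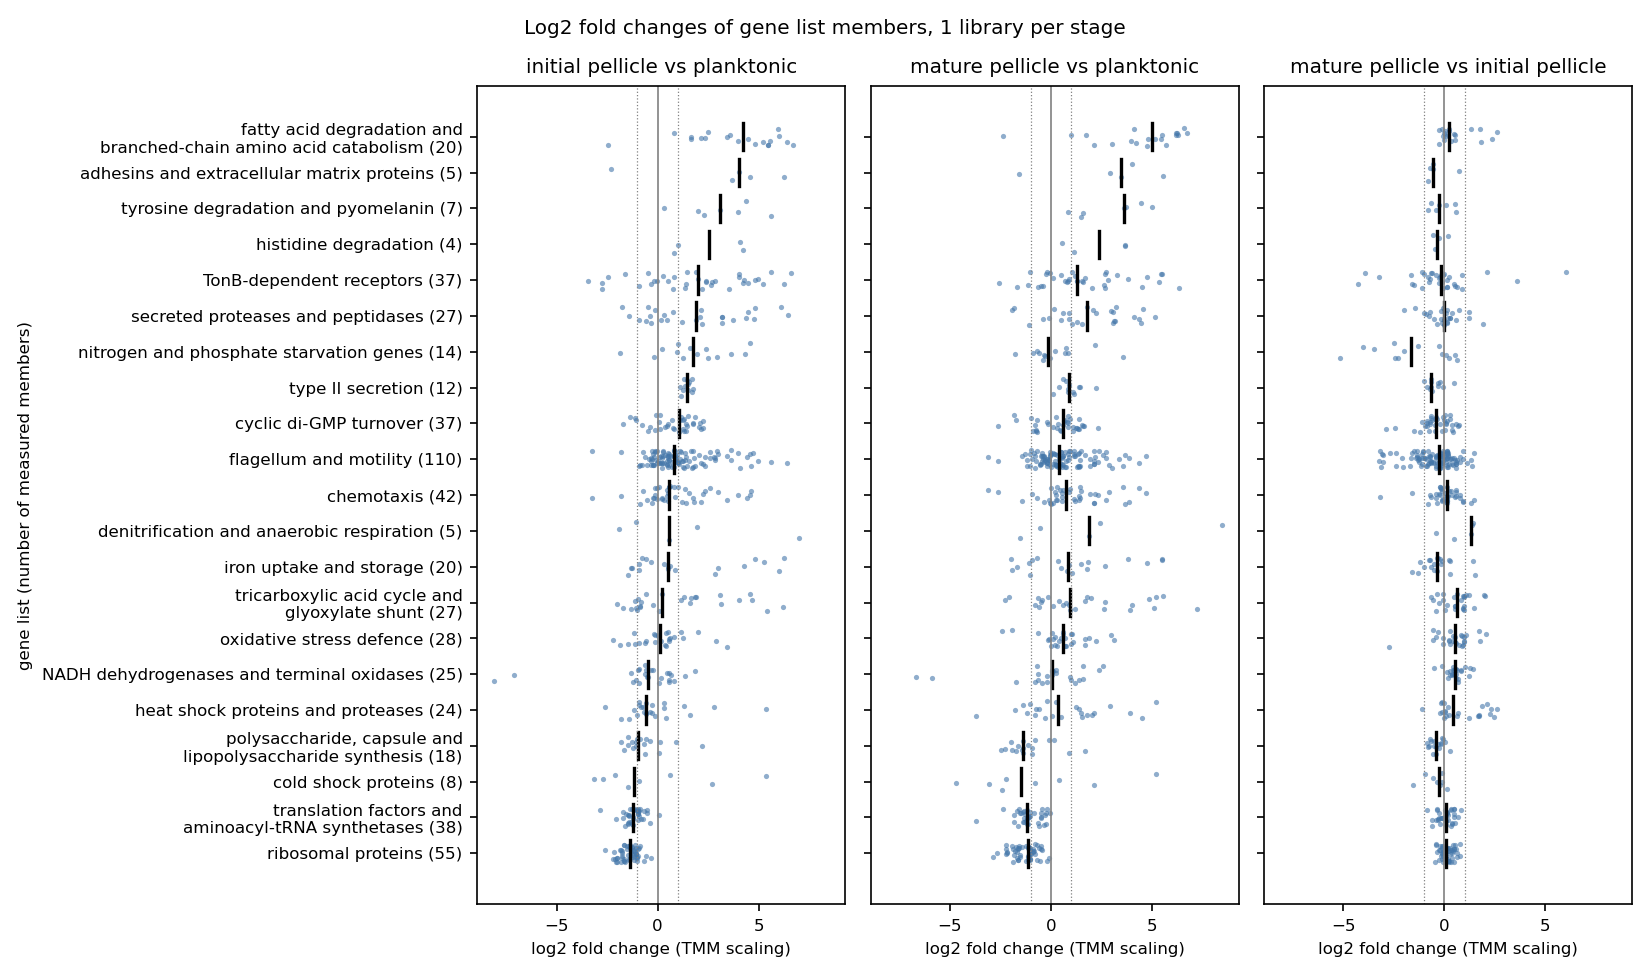
Log2 fold changes (horizontal axis, TMM scaling) of the members of 21 gene lists in the 3 comparisons, with 1 point per gene, a black bar at the list median, a solid line at 0 and dotted lines at 2-fold; the number of measured members stands in brackets, and the flagellum list is drawn as fixed, with the chemotaxis genes it caught. The medians of 4.21 and 4.98 for fatty acid and branched-chain amino acid catabolism lie far to the right against planktonic cells, and those of -1.39 and -1.13 for ribosomal proteins lie to the left.

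The comparison of the mature pellicle with planktonic cells asked what set the biofilm apart after 5 days. Genes of the pooled list for breakdown of fatty acids and branched-chain amino acids, and those for tyrosine breakdown, were higher in the mature pellicle. So was the glyoxylate shunt, with isocitrate lyase PSM_B0064 at 148-fold. Outer membrane protein W (PSM_A0976) was 520-fold higher, the largest difference with a known product. The cytochrome o oxidase genes were 58.4-fold to 291-fold lower, and 39 of 55 ribosomal protein genes were lower, or 26 with total counts. In all, 1010 genes were at least 2-fold higher and 891 at least 2-fold lower of 3552.

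Of the 20 genes for fatty acid and branched-chain amino acid catabolism, 19 were higher and 1 lower (median 4.98, percentile 100), with PSM_A1501 at 105-fold (interval 6.47 to 7.01) and PSM_A1500 at 96.7-fold. In tyrosine degradation 6 of 7 genes were again higher (median 3.63, percentile 99.95). The dioxygenases PSM_A0972 and PSM_B0404 were 31.5-fold and 21.9-fold higher, PSM_B0403 13.2-fold and PSM_A0971 12.4-fold. PSM_A2106 and PSM_A2107 were 2.95-fold and 2.80-fold higher, and PSM_A0663 had a log2 fold change of 0.85. For the tricarboxylic acid cycle and glyoxylate shunt, 13 of 27 genes were higher and 2 lower (median 0.96, percentile 99.6). Malate synthase PSM_B0063, the second step of the shunt, was 45.9-fold higher. This list and the histidine list (3 of 4 higher, median 2.40, percentile 98.9) both lay at percentile 97.2 among runs of neighbouring genes, inside their central 95%. Histidine genes PSM_A0286 and PSM_A0287 were 12.6-fold and 12.5-fold higher. Alcohol dehydrogenase PSM_B0592 was 351-fold higher (8.11 to 8.92), aldehyde dehydrogenase PSM_B0267 279-fold (7.94 to 8.34), the CBS domain gene PSM_A2505 204-fold and the decarboxylase PSM_B0022 181-fold. In glycolysis and gluconeogenesis 4 of 11 genes were higher and 2 lower (median 0.89, percentile 96.2), with glyceraldehyde-3-phosphate dehydrogenase PSM_A1145 at 4.60-fold higher and triosephosphate isomerase PSM_A2172 at 5.79-fold lower.

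TonB-dependent receptors had 21 of 37 genes higher and 4 lower (median 1.29, percentile 99.98), including PSM_A2033 at 81.5-fold (6.27 to 6.43). Iron genes had 9 of 20 higher and 5 lower (median 0.85, percentile 97.3), with PSM_A2366 and PSM_A1233 at 44.6-fold and 44.3-fold higher. The adhesin and matrix list, again through its curli genes, had 4 of 5 members higher and 1 lower (median 3.46, percentile 99.8). PSM_B0249 was 46.3-fold and PSM_B0247 16.2-fold higher. Proteases and peptidases had 17 of 27 higher and 3 lower (median 1.78, percentile 99.99), deseasin PSM_B0251 by 35.0-fold and the leucine aminopeptidase-related PSM_A1346 by 23.8-fold. Type II secretion had 5 of 12 higher and 0 lower (median 0.87, percentile 92.7), with PSM_A0730 at 4.63-fold. Chemotaxis genes had 19 of 42 higher and 3 lower (median 0.76, percentile 98.4; 97.4 among runs of neighbours, inside the central 95%). PSM_A2360 was 25.9-fold and PSM_A1514, also a methyl-accepting transducer, 20.6-fold higher. Flagellum and motility genes without the chemotaxis overlap had 16 of 69 higher and 5 lower (median 0.15, percentile 61.8), and the list as fixed had 34 of 110 higher and 8 lower (median 0.39, percentile 95.3). Pilus genes had 5 of 17 higher and 0 lower (median 0.85, percentile 94.4), pilin PSM_A2709 by 10.2-fold. Cyclic di-GMP genes had 11 of 37 higher and 3 lower (median 0.61, percentile 90.0), with PSM_B0156 at 5.03-fold higher and the GGDEF gene PSM_A3038 at 6.05-fold lower. Nitrogen and phosphate starvation genes had 2 of 14 higher and 1 lower, with a median of -0.16 that became 0.05 with total counts. The exopolyphosphatase-related gene PSM_A2305 was 11.7-fold higher.

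Polysaccharide genes had 11 of 18 lower and 1 higher (median -1.38, percentile 0.2), PSM_A1270 by 5.62-fold and the exopolysaccharide gene PSM_A1269 by 4.86-fold. The ribosomal list had a median of -1.13 (percentile 0) with 0 of 55 genes higher, and L34 (PSM_A3127) and L31 (PSM_A0299) were 7.33-fold and 6.29-fold lower. Translation factors and synthetases had 25 of 38 lower and 0 higher (median -1.18, percentile 0.04), IF-1 (PSM_A1316) by 13.2-fold and elongation factor G (PSM_A0241) by 5.11-fold. With total counts, 26 ribosomal and 16 translation genes were lower. ATP synthase genes had 2 of 9 lower and 0 higher (median -0.34, percentile 52.1). In the oxidase cluster PSM_A0857 was 291-fold lower, PSM_A0856 234-fold, PSM_A0855 169-fold, PSM_A0858 101-fold, PSM_A0860 69.4-fold and PSM_A0859 58.4-fold. The NADH dehydrogenase and oxidase list had 6 of 25 higher and 3 lower (median 0.06, mean -0.18, percentile 54.9). Cold shock genes had 4 of 8 lower and 2 higher (median -1.49, percentile 0.79), with PSM_B0051 at 25.7-fold lower and PSM_A1312 at 36.9-fold higher. Heat shock proteins and proteases had 11 of 24 higher and 5 lower (median 0.37, percentile 89.8), the Hsp100 chaperone PSM_A1008 by 22.9-fold. Oxidative stress genes had 9 of 28 higher and 2 lower (median 0.59, percentile 92.6), with catalase PSM_B0093 at 7.96-fold. With total counts, 10 pilus and 8 type II secretion genes were higher, and the lower members numbered 4 in the flagellum list as fixed, 2 in TonB-dependent receptors, 3 in iron, 3 in heat shock and 1 in ATP synthase genes. Of the 28 lists, 8 had medians above and 5 below the central 95% of random lists, and 5 lay above it against runs of neighbouring genes. After the same partial correction, which removed the toxin-antitoxin list, 8 of 27 lay above and 4 below. The 8 include the tricarboxylic acid cycle list, which was left as fixed with its leucine synthesis and methylcitrate genes. The authors' deposited table for this comparison had 1177 of 3629 genes higher and 742 lower by the same limits.

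The comparison of the mature with the initial pellicle asked what differed within the biofilm between 1 and 5 days. Genes for phosphate scavenging, arginine synthesis, the TonB-linked cluster and the lateral flagellum were lower in the mature pellicle. Of 24 heat shock proteins and proteases, 10 were higher and 1 lower. PSM_B0604 was 125-fold lower and a TonB-dependent receptor, PSM_A0931, 63.8-fold higher (interval 5.92 to 6.08). Fewer genes passed the threshold than against planktonic cells, with 295 higher and 218 lower of 3552.

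Nitrogen and phosphate starvation genes had 8 of 14 lower and 0 higher (median -1.64, percentile 0). The alkaline phosphatases PSM_A3086 and PSM_A3085, which release phosphate from organic compounds, were 35.3-fold and 16.3-fold lower. Acetylglutamate kinase PSM_A0796 and ornithine carbamoyltransferase PSM_A0797, both of arginine synthesis, were 40.5-fold lower each (-5.64 to -5.10 and -5.53 to -5.17). In the TonB-linked cluster PSM_B0605 was 72.5-fold and the lipoprotein PSM_B0609 33.0-fold lower. Flagellum and motility genes without the chemotaxis overlap had 29 of 69 lower and 2 higher (median -0.75, percentile 0; -0.27 in the list of 110 as fixed, with 30 lower, 4 higher and percentile 0.01), PSM_A0891 by 9.28-fold and the lateral motor gene PSM_A0905 by 9.08-fold. Cyclic di-GMP genes had 5 of 37 lower and 0 higher (median -0.43, percentile 0.14), PSM_A0906, with a PilZ domain, by 7.30-fold and PSM_A2769 by 5.34-fold. PSM_A0906 had 121 counts in the initial and 11 in the mature pellicle, and it lies in the lateral flagellum run (PSM_A0884 to PSM_A0920). Type II secretion had 1 of 12 lower, PSM_A0734 by 2.02-fold (median -0.64, percentile 0.12). Iron genes had 4 of 20 lower and 2 higher (median -0.36, percentile 0.21), with the siderophore receptor PSM_A0022 at 3.04-fold lower and bacterioferritin PSM_B0359, an iron store, at 2.84-fold higher. Both of these lists moved inside the central 95% against runs of neighbouring genes (percentiles 3.62 and 3.21). The polysaccharide list had 0 of 18 genes past the threshold (median -0.40, percentile 0.83).

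The lists for heat shock, oxidative stress, the tricarboxylic acid cycle, NADH dehydrogenases and oxidases, and anaerobic respiration had medians above the central 95% of random lists, and that of ATP synthase did not. Heat shock proteins and proteases had 10 of 24 higher and 1 lower (median 0.43, percentile 98.6), with the chaperones GroES (PSM_A2831) at 6.02-fold and DnaK (PSM_B0426) at 5.53-fold. The heat shock sigma factor, sigma-32 (PSM_A2732), was 3.33-fold higher. Oxidative stress genes had 4 of 28 higher and 1 lower (median 0.53, percentile 99.98), with glutaredoxin PSM_A2723 at 4.19-fold higher and glutathione peroxidase PSM_A1761 at 6.60-fold lower. The tricarboxylic acid cycle list had 5 of 27 higher and 0 lower (median 0.63, percentile 99.97), fumarate hydratase PSM_A0050 by 4.08-fold and aconitate hydratase PSM_A0172 by 3.93-fold. NADH dehydrogenases and oxidases had 4 of 25 higher and 0 lower (median 0.52, percentile 99.4), PSM_A2965, a cytochrome c oxidase subunit, by 2.30-fold. The bd-type oxidase genes PSM_A2081 and PSM_A2082, which this list missed, had a median of 6.31-fold higher. ATP synthase genes had 2 of 9 higher (median 0.61, percentile 96.5), PSM_A3106 by 2.36-fold and PSM_A3107 by 2.12-fold. The list named for denitrification and anaerobic respiration, made up mostly of alcohol and lactate dehydrogenases, had 3 of 5 higher (median 1.31, percentile 99.8), PSM_B0592 by 2.72-fold and PSM_A2483 by 2.61-fold. Phosphogluconate dehydratase PSM_A1394, of the Entner-Doudoroff route of sugar breakdown, was 14.5-fold higher and glyceraldehyde 3-phosphate dehydrogenase PSM_A1396 13.9-fold. The receptor PSM_B0240, the oxidoreductase subunit PSM_B0187 and PSM_A0214, of arginine breakdown, were 12.2-fold, 10.8-fold and 9.62-fold higher. TonB-dependent receptors had 3 of 37 higher and 9 lower (median -0.17, percentile 3.68), with PSM_B0315 at 19.3-fold lower.

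The lists that follow had medians inside the central 95% of random lists. Catabolism of fatty acids and branched-chain amino acids had 5 of 20 higher and 0 lower, among them acyl-CoA dehydrogenase PSM_B0445 (6.01-fold) and thiolase PSM_A0011 (5.05-fold), with a median of 0.22 that became -0.12 with total counts. No gene of tyrosine degradation passed the threshold (0 of 7; median -0.26, percentile 8.66). Its log2 fold changes ran from -0.82 in PSM_A2107 and -0.64 in PSM_A0972 over -0.43 in PSM_A2106 and -0.26 in PSM_B0403 to 0.51 in PSM_A0663 and 0.56 in PSM_A0971. PSM_B0404 stood at 0.07, which became -0.27 with total counts. Ribosomal proteins and translation genes had 0 members past the threshold, and their medians of 0.10 and 0.09 became -0.24 and -0.25 with total counts. Chemotaxis (2 higher and 2 lower, 0.11), pilus (1 and 1, 0.13) and glycolysis genes (2 and 0, 0.18) also had medians that turned negative under that scaling, at -0.23, -0.21 and -0.16. Pilin PSM_A2709 was 2.89-fold and pyruvate kinase PSM_A1444 4.28-fold higher. Proteases had 3 of 27 higher and 2 lower (median 0.00), cold shock genes 1 of 8 lower (-0.28), histidine genes 0 of 4 past the threshold (-0.35) and adhesins 0 of 5 (-0.57). Of the 28 lists, 5 lay above and 6 below the central 95%. With total counts, the lower members numbered 13 in cyclic di-GMP, 7 in iron, 5 in type II secretion, 6 in proteases, 4 in polysaccharide, 4 in chemotaxis, 2 in adhesin, 2 in cold shock, 1 in tyrosine and 1 in translation genes, and the higher ones 1 in proteases, 1 in chemotaxis, 2 in the flagellum list as fixed, 3 in the tricarboxylic acid cycle, 1 in the NADH dehydrogenase and oxidase list and 0 in ATP synthase. Under that scaling 187 genes were higher and 512 lower in all, so that 26.8% of the genes past the threshold were higher against 57.5% in the main scaling.

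Runs of neighbouring genes, chosen after their values had been seen, gave a closer view of these groups, and each fold given for a run is the median over its genes. The lateral flagellum run (PSM_A0884 to PSM_A0920) had 34 of 37 genes higher in the initial pellicle than in planktonic cells, with a median of 7.74-fold. In the mature pellicle 16 were higher than in planktonic cells, and 32 were lower than in the initial pellicle, with a median of 5.17-fold lower. The polar flagellum run (PSM_A2239 to PSM_A2299) had 9 of 60 genes higher and 3 lower in the initial pellicle (median log2 fold change 0.22) and 9 higher and 9 lower in the mature pellicle (median -0.25), against 26 higher and 0 lower, then 12 higher and 4 lower, with total counts. Arginine synthesis (PSM_A0794 to PSM_A0799) had a median of 87.5-fold higher in the initial and 2.72-fold higher in the mature pellicle. Arginine breakdown by the succinyltransferase route (PSM_A0212 to PSM_A0214) had the opposite profile, with 7.53-fold lower in the initial pellicle and 9.41-fold higher in the mature than in the initial pellicle. The Entner-Doudoroff run (PSM_A1394 to PSM_A1396) was likewise 12.0-fold lower in the initial pellicle, and 13.9-fold higher in the mature than in the initial pellicle. Its member PSM_A1396, a glyceraldehyde 3-phosphate dehydrogenase, also stands in the glycolysis list. Cytochrome o oxidase genes (PSM_A0855 to PSM_A0860) had medians of 180-fold and 130-fold lower than planktonic. The bd-type oxidase genes PSM_A2081 and PSM_A2082, which encode a terminal oxidase of high oxygen affinity in many bacteria, had medians of 7.90-fold higher in the initial and 49.8-fold higher in the mature pellicle than in planktonic cells. Of the 4 genes of the cbb3-type oxidase (PSM_A1217 to PSM_A1220), also a terminal oxidase, 0 passed the threshold in the initial pellicle (median log2 fold change 0.50) and 2 were higher in the mature pellicle (1.09), against 3 in each with total counts. The TonB-linked run (PSM_B0603 to PSM_B0610) was 62.3-fold higher in the initial pellicle and 27.9-fold lower in the mature than in the initial pellicle. A run named for lysine monooxygenase (PSM_B0022 to PSM_B0027), which includes the putative decarboxylase PSM_B0022, was 91.6-fold and 103-fold higher than planktonic. Branched-chain amino acid genes (PSM_A1495 to PSM_A1504) were 39.9-fold and 42.8-fold higher. In a polysaccharide run (PSM_A0437 to PSM_A0453), 16 of 17 genes were lower in each pellicle, against 4 and 12 with total counts. An exopolysaccharide run (PSM_A1269 to PSM_A1285) had 8 and 12 of 15 genes lower, against 2 and 10 with total counts.

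**Figure D2:**
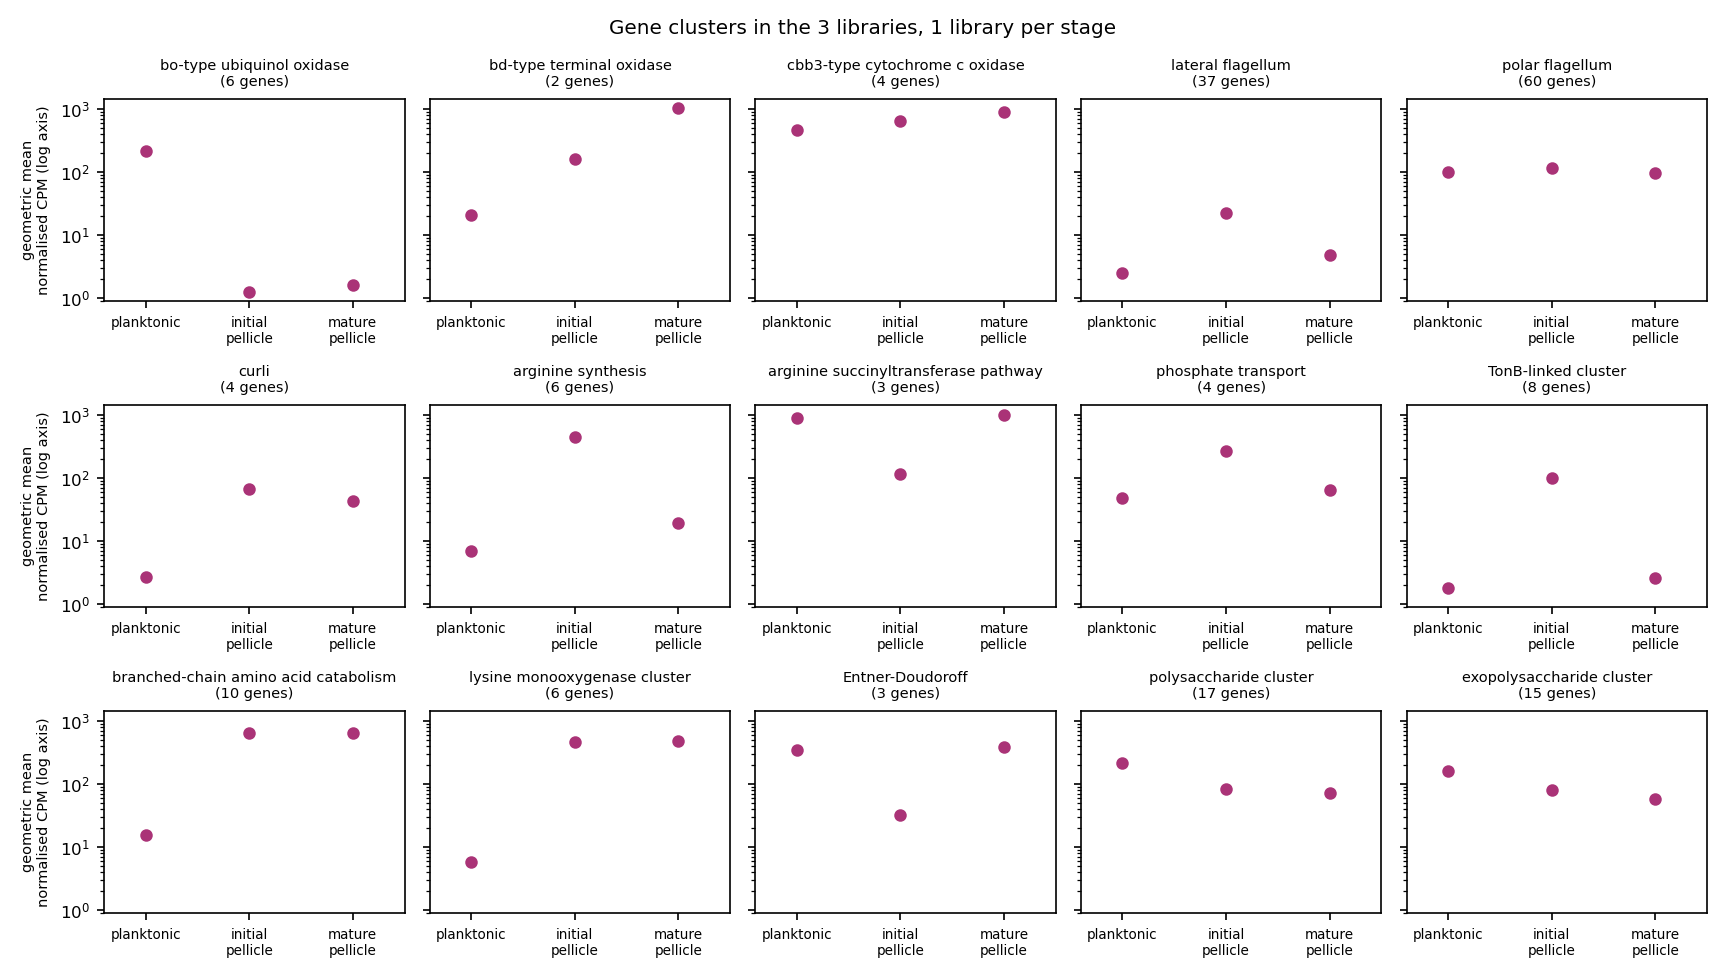
Geometric mean of normalised CPM (vertical log axis) over the genes of 15 runs of neighbouring genes in the planktonic, initial pellicle and mature pellicle libraries, with 1 point per library and no error bars because each stage had 1 library. The cytochrome o (bo-type) oxidase is 180-fold and 130-fold lower in the pellicles by its median gene, while the lateral flagellum and arginine synthesis are highest in the initial pellicle.

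Both pellicle comparisons share the planktonic library, so part of any overlap arises from it. At least 2-fold higher in both pellicles were 765 genes and at least 2-fold lower 689, against 265 and 209 if the lists were independent. Simulated unchanged pellicles set against the same planktonic library gave 0.58 and 0.21 such genes with counting error only, 8.4 and 3.94 with an assumed biological coefficient of variation of 0.2, and 174.65 and 117.05 with 0.4. The covariance of the log2 fold changes across genes was 2.90, against simulated values of 0.0158, 0.0989 and 0.370. The correlation across genes, which are not independent replicates, was 0.883 (simulated 0.580, 0.511 and 0.504). The shared higher genes held all 4 genes of the curli run, all 10 of the branched-chain amino acid run and 6 of 7 tyrosine genes, and the shared lower genes all 6 of the cytochrome o oxidase run. Genes that set 1 pellicle apart numbered 137 higher and 65 lower in the initial pellicle than in both other libraries, and 209 higher and 56 lower in the mature pellicle. With 1 planktonic library the controls could not be divided, and part of the excess may come from the shared library.

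**Figure D3:**
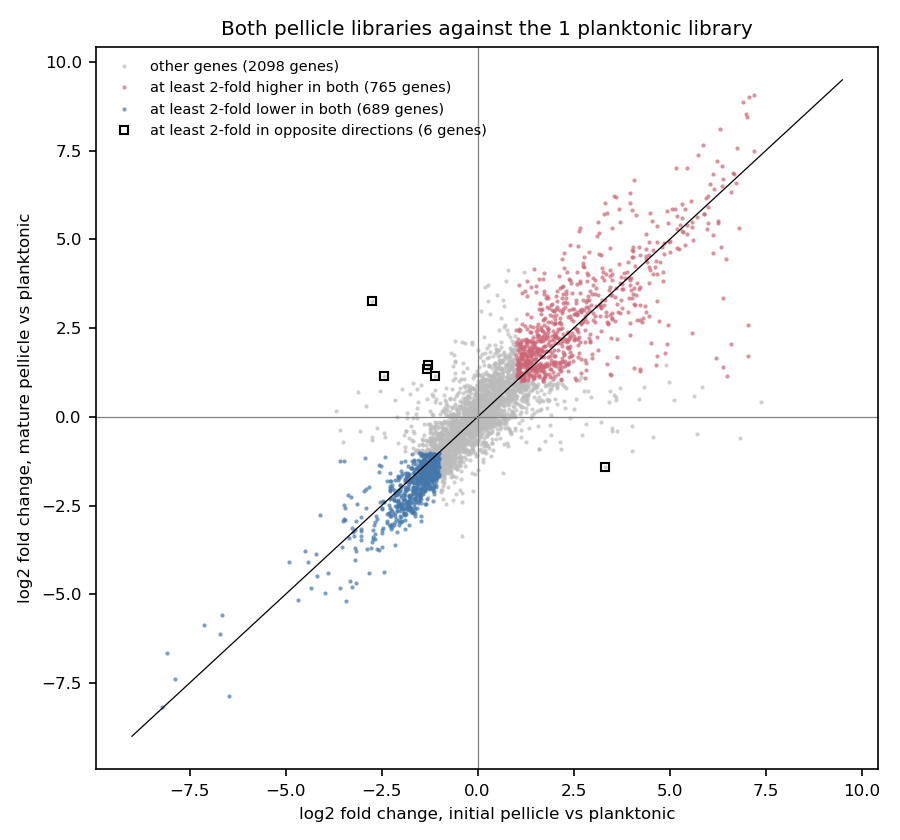
Log2 fold change of each of 3552 genes in the mature pellicle (vertical axis) against that in the initial pellicle (horizontal axis), both relative to the 1 planktonic library, with the diagonal drawn. Coloured points mark 765 genes at least 2-fold higher and 689 at least 2-fold lower in both, and squares mark 6 genes at least 2-fold in opposite directions.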

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

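The tests of background, scaling and adjacency were chosen after the results they bear on had been seen. The TonB-dependent receptor gene PSM_A0931 stood out because it differed from planktonic cells in opposite directions in the pellicles, with log2 fold changes of -2.74 in the initial and 3.26 in the mature pellicle. The receptor gene PSM_B0240 did the same, at -2.44 and 1.17. With 1 library per stage the difference between the pellicles was not tested in either case. Simulated unchanged pellicles gave 0 genes with opposite directions with counting error only and 0.01 with an assumed biological coefficient of variation of 0.2. With 0.4 they gave 9.68, against 6 observed. These numbers take in any gene at least 2-fold each way, so they cannot weigh the size of the difference in either receptor gene. Between the pellicles PSM_A0931 differed 63.8-fold and PSM_B0240 12.2-fold. Counts were 5435, 1283 and 62614 for PSM_A0931 and 3804, 1105 and 10286 for PSM_B0240 in planktonic, initial and mature libraries.

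At 4-fold the pellicles had more higher than lower genes against planktonic cells, 465 against 175 in the initial and 499 against 284 in the mature pellicle. With total counts these were 671 against 80 and 576 against 211. A uniform background of reads, such as genomic DNA, would add about the same RPKM to every gene, but in both pellicles 100% of the 4-fold higher genes exceeded their planktonic RPKM by more than the 1st percentile of RPKM among genes of at least 1000 bases, which was 2.63 and 2.01, while their median excess was 149 and 156, which argues against such a background as the whole cause. Equal numbers would need log2 values lower by 0.42 in the initial and 0.29 in the mature pellicle, while the scalings tried lowered them by at most 0.0418, which argues against the choice among these scalings. The absolute amount of RNA per cell was not measured, so a shift of that size may exist, and a biological difference between the stages stays open as untested.

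A set of 56 genes was at least 4-fold higher in the initial pellicle than in both other libraries, among them lateral flagellar, arginine synthesis, phosphate and thiamine genes. Of these, 83.9% lay directly beside another member, against a median of 3.57% and a highest value of 21.4% among 10000 random sets matched on expression. That argues against noise that strikes genes singly. Because there was only 1 initial pellicle library, a property of this 1 culture or library other than its stage cannot be told apart from the stage. A response of the early pellicle may underlie the set, as a hypothesis that a second culture could test.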

How the results depend on the processing

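No paired analysis was possible because each stage had 1 library and no result came from a test, and leaving out a library or splitting the samples was impossible for the same reason. With a 4-fold threshold the counts were 465 higher and 175 lower for initial against planktonic, 499 and 284 for mature against planktonic and 76 and 64 for mature against initial, and the shared genes numbered 488 in place of 1454. At 4-fold with total counts the higher and lower genes of these comparisons numbered 671 and 80, 576 and 211, and 47 and 77, so that the last comparison had more lower than higher genes. At 2-fold with total counts, 371 genes in place of 835 were lower in the initial pellicle than in planktonic cells, and 187 higher and 512 lower in place of 295 and 218 in the mature than in the initial pellicle. The authors' deposited log2 ratio, for which no table of mature against initial was used, gave 372 lower genes in the initial pellicle. By construction, scaling by totals, which the RPKM behind that ratio share, moves the log2 scale of a comparison as a whole, though not by the same amount for genes with few counts. The other counts of genes past 2-fold, and the total number of lists outside the central 95% in each comparison, stayed within 1.5 times of the main ones under every alternative, and so did the shared count with total counts (1365). A shift of the whole scale moves random lists along with each list. The number of lists outside could therefore hardly change under the other scalings. Against runs of neighbouring genes, 5 lists in place of 8 lay above the central 95% in the mature pellicle against planktonic cells. Total counts moved 155 of the named log2 fold changes and 81 list medians beyond counting error, DESeq2 size factors 35 and 21, and the authors' ratio 97 and 54. No filter and a prior count of 0.5 moved none of them, but without a filter 9 lists in place of 8 lay above the central 95% in the mature pellicle against planktonic cells, the added one being that of anaerobic respiration. A minimum of 100 counts moved 4 list medians and 0 named genes. Over all comparisons these runs made 8 list medians change sides of the central 95%: 7 moved inside and that of cold shock proteins in the initial pellicle moved outside (percentile 1.41). Keeping ribosomal and transfer RNA genes in could not be run, as the table held 0. The corrected lists, chosen after the data were seen, moved 3 medians. Counting intervals excluded 1 for 89.4%, 89.4% and 81.0% of genes in the 3 comparisons, and for the others a difference was not detectable at this depth. The spread between cultures was not measured.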

Other observations

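The test of position here was chosen before its result was seen, and the other values were looked at after the main results. The PSM_B series of genes, which follows a separate tag series from PSM_A, stood higher in both pellicles. Its median log2 fold change over 589 genes was 0.61 in the initial and 0.71 in the mature pellicle against planktonic cells, compared with -0.13 and -0.05 over 2963 PSM_A genes. In the initial pellicle 39.9% of PSM_B genes were at least 2-fold higher and 13.4% lower, compared with 23.6% and 25.5% of PSM_A genes. In the mature pellicle these shares were 42.1% and 15.1% for PSM_B, 25.7% and 27.1% for PSM_A. Between the pellicles the medians were both -0.02.

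The lists that follow had medians inside the central 95% of random lists in the comparisons with planktonic cells given here, except that the anaerobic respiration list in the mature pellicle lay above it without a filter on low counts. Multidrug efflux genes had 11 of 45 higher and 9 lower in the initial pellicle (median 0.06) and 10 higher and 10 lower in the mature pellicle, with a median of -0.09 that became 0.12 with total counts. Among them the pump gene PSM_A0812 was 11.4-fold higher in the initial pellicle, and the efflux lipoprotein PSM_B0441 was 15.0-fold and 21.0-fold lower. Mobile elements had 4 of 26 higher and 4 lower in the initial and 5 and 4 in the mature pellicle (medians 0.21 and 0.15), and a transposase gene of the IS66 type, PSM_A2523, was 9.86-fold and 14.6-fold higher. Sigma factors had 2 of 9 higher and 1 lower, then 4 higher and 1 lower (medians 0.30 and 0.55), with PSM_A1230 at 11.4-fold and 7.62-fold higher. In the mature against the initial pellicle the medians of efflux, mobile element and sigma factor genes were -0.22, -0.07 and 0.03, the last becoming -0.31 with total counts. With total counts the mobile element list had 8 genes higher and 2 lower in the initial pellicle, sigma factors 3 and 0, and efflux genes 16 and 7 there and 17 and 8 in the mature pellicle. In the initial pellicle, heat shock genes had 4 of 24 higher and 5 lower (median -0.59) and oxidative stress genes 5 of 28 higher and 5 lower (median 0.13), against 4 and 2 (median -0.04) and 10 and 2 (median 0.68) with total counts. The list named for anaerobic respiration had 2 of 5 genes higher and 2 lower in the initial pellicle and 3 higher and 1 lower in the mature pellicle (medians 0.57 and 1.88), against 3 higher and 1 lower in each with total counts. Genes chosen after their values were seen include 4 others with opposite directions in the pellicles: the glycosyl hydrolase gene PSM_B0275 (-1.30 and 1.46), and the hypothetical genes PSM_A1714 (-1.11 and 1.16), PSM_A2018 (-1.31 and 1.36) and PSM_A2431 (3.31 and -1.40). In all, 6 genes had opposite directions, against 0 in simulated unchanged pellicles with counting error only, 0.01 with an assumed biological coefficient of variation of 0.2 and 9.68 with 0.4.

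Fast-growing bacteria carry extra copies of genes near the replication origin, so a hypothesis was that log2 fold changes would increase with distance from the first PSM_A tag, a DnaA gene. The log2 slope from that tag to the opposite side of the gene order was 0.28 in the initial and 0.16 in the mature pellicle. Among circular shifts of the gene order these slopes lay at percentiles 96.6 and 98.6, and the bound set beforehand, the upper end of the central 95% of shifts, was passed in the mature pellicle only. Without translation genes the slopes were 0.23 and 0.12. Spearman's rank correlation of log2 fold change with distance in gene order was only 0.045 in the initial and 0.016 in the mature pellicle. A lower copy number near the origin may contribute, but the values do not decide it.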
